A study of Homo sapiens with 6 samples.

How the data were processed

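RNA sequencing libraries were made from total RNA of cells given as LNCaP, 3 from cells given an empty vector and 3 from cells given a LINC01518 overexpression vector, per the labels. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the human genome build GRCh38 with HISAT2 and counted per gene with featureCounts of Subread 1.5.1, and DESeq was used. The deposited gene counts were whole numbers with no normalization applied, and every test described as made on counts started from them. The deposited TPM values, 1 per gene and library, were used only in alternative fits. The tool that made the TPM, the annotation release and the strand setting of the counting are not given in the sources used here. Among the 10545 genes with at least 200 counts in each library, the SD between libraries of the log2 ratio of count to TPM had a median of 0.0347 and a 90th percentile of 0.148, so the deposited TPM were not a rescaling of the counts by 1 fixed length per gene. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart in the counts, and reads shared by near-identical copies can be divided between them.

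The table held 20263 genes, of which 19722 were annotated as protein-coding, 16 as lincRNA and 6 as antisense RNA. Symbols were taken for 20148 genes from a gene name table and positions for 20224 genes from GENCODE release 29, build GRCh38. All 6 count columns and 6 TPM columns were assigned to samples by name, and 0 columns were left unmatched. LINC01518, MEG3 and the lists of nuclear non-coding RNAs and of prostate cancer long non-coding RNAs were not analysed here.

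Total counts per library lay between 38161544 and 42553688. A count of 0 allowed up to 3 counts, which corresponded to 0.0705 to 0.0786 CPM (counts scaled to library size), depending on the library. This floor covers counting error only. Replicates were not paired in the model, since the labels do not say that a shared number marks a shared culture or day.

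Differential expression was computed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count of 10 and minimum total of 15), which left 13543 genes, and libraries were scaled by TMM. A robust quasi-likelihood model with the group as its only term was fitted to all 6 libraries and tested with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Log2 fold changes are overexpression minus empty vector, CPM are TMM-scaled, and the spread given beside a mean is the SD of 3 libraries.

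A total of 32 gene lists were written before the data were examined, as were the main tests, the rule for named genes and every alternative except the correction for GC content and length. Lists with at least 5 tested genes, 29 in all, were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. Camera asks whether a list's genes moved against all other genes. The test was repeated with a correlation estimated per list. Fry was run as a different test, which asks whether a list's genes moved, on balance, in 1 direction and does not compare them with other genes. The rule for named genes took prostate genes fixed in advance, KLK3, TMPRSS2 and FKBP5 among them. It added the 8 called genes with the largest fold change in each direction among those with a mean log2 CPM of at least 1 and no overlap between the groups, and the 5 with the smallest p in each direction. It further added up to 4 genes of each called list and up to 2 genes of any other list with at least 3 called members. The rule gave 82 genes, of which 80 were tested, and some of these and 1 gene list are not reported here. Genes named outside the rule are members of the fixed lists or were chosen after their values were seen.

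The fits were tested on simulated counts for the 13543 genes, drawn with the means and sizes of these libraries and with 200 genes changed. In the simulated comparison of overexpression with empty vector, edgeR recovered 14% of the 50 genes given the smallest change, which was below 1.5-fold, 52% at 1.5-fold, 88% at 2-fold and 90% at 4-fold, with 0 of the wrong sign. It called 6 of the 13343 simulated genes that were left as they were. In simulated lists, camera, camera with an estimated correlation and fry each called the shifted list and 0 of the 40 other lists. The means and sizes of these libraries were given to the simulated counts, but not the correlation between members of a list. The check therefore cannot tell whether the preset or the estimated correlation suits the real libraries. There, camera called 11 lists with the preset correlation and 0 with the estimated one.

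The alternatives were RLE scaling, upper-quartile scaling, library size only, no count filter, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), the replicate number as a block, each library left out in turn, a test against a 1.5-fold change (glmTreat), and a fit without mitochondrially encoded and ribosomal protein genes. A fit corrected with splines (5 degrees of freedom) of GC content and transcript length was chosen after seeing the data. GC content and length were at hand for 13529 of the 13543 genes tested.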

Results

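Gene expression was measured by RNA sequencing of total RNA from cells that the labels give as LNCaP, an established cell line from human prostate cancer described as androgen-responsive. Per the labels, 3 libraries came from cells given an empty vector and 3 from cells given a vector to overexpress LINC01518, a long non-coding RNA. The series description names MEG3, another long non-coding RNA, as the insert, whereas the title and the sample labels name LINC01518, and the groups are called here by the sample labels. Neither RNA was analysed here, so the level of the insert was not checked. The empty vector libraries held 40259223, 42229418 and 38541029 counts, and the overexpression libraries held 42553688, 39771573 and 38161544. A count of 0 in a library allowed up to 0.0705 to 0.0786 CPM, for counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical alone.

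The comparison asked which genes changed when the overexpression vector was given. GNA12, which encodes the alpha subunit of the G protein G12, fell from 76.7 ± 3.68 CPM (SD, n = 3) with empty vector to 17.2 ± 0.821 CPM (SD, n = 3) with overexpression, a 4.46-fold fall. PDK4, which encodes a kinase that inhibits pyruvate dehydrogenase, rose from 84.2 ± 2.36 to 170.9 ± 5.52 CPM (SD, n = 3 each). Of the stress genes, 11 of 26 of the endoplasmic reticulum list, among them the chaperone gene HSPA5 (2862 ± 73.8 to 1714 ± 55.3 CPM, SD, n = 3 each), and 13 of 33 of the integrated stress response list fell, and both lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.106 for each). Of the metabolic genes, 10 of 26 of cholesterol synthesis, 8 of 21 of fatty acid synthesis and 12 of 36 of hypoxia and glycolysis rose, and these lists passed camera likewise but not with an estimated correlation (adjusted p = 0.191, 0.106 and 0.288). KLK3 and TMPRSS2, hallmark androgen-induced genes of the prostate, had 0 counts in all 6 libraries.

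Of 13543 genes tested with edgeR, 759 had an adjusted p under 0.05, 484 higher and 275 lower with overexpression. Most changes were small, with a median absolute log2 fold change of 0.37 among the called genes and 40 genes changed at least 2-fold, 30 of them higher. The 3 libraries of each group lay apart from those of the other for 759 of the 759 called genes, which the selection by p-value favours. They lay apart for 31.4% of all genes tested, where chance gives 10% on average. Genes are not independent, so this share is a description and not a test. GNA12 (chromosome 7, 2728112 to 2844324, GRCh38) had a log2 fold change of -2.16 (SE 0.068, edgeR adjusted p = 1.46e-05), and part of it overlaps AMZ1 on the opposite strand, which had 16 to 34 counts per library. SERPINH1, which encodes a collagen chaperone (chromosome 11, 75562056 to 75572783), fell from 85.9 ± 4.05 to 44.9 ± 1.23 CPM (edgeR adjusted p = 5.27e-04). TGM2, the gene of a transglutaminase, fell from 269 ± 7.88 to 166 ± 2.75 CPM. SERPINE2, a serine protease inhibitor gene, fell by 0.90 on the log2 scale and IL20RB, a cytokine receptor gene, by 0.81. FGFBP1, which encodes a carrier of fibroblast growth factors (chromosome 4, 15935569 to 15938740), rose from 15.4 ± 0.991 to 41.1 ± 3.48 CPM, a log2 fold change of 1.42 (SE 0.086, edgeR adjusted p = 5.27e-04). PDK4 (chromosome 7, 95583499 to 95596491) had a log2 fold change of 1.02 (SE 0.048, edgeR adjusted p = 1.71e-04). PTGS1, which encodes cyclooxygenase-1, rose from 925.5 ± 25.3 to 1403 ± 28.0 CPM. The splicing factor gene SRRM4 (log2 fold change 1.71) and the insulin-like peptide gene INSL4 (1.33) rose from lower levels, 1.34 and 5.05 CPM. Against a fold change of 1.5, edgeR called GNA12, PDK4 and FGFBP1, and 0 other genes passed among 159 at an unadjusted p under 0.05.

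**Figure D1:**
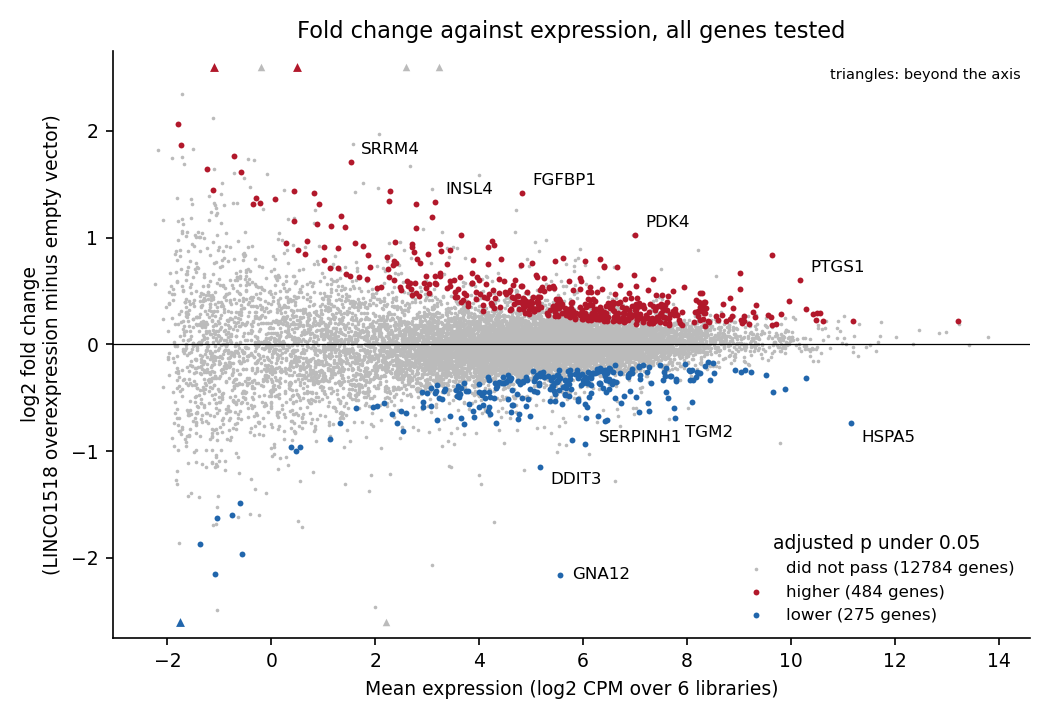
Log2 fold change (overexpression minus empty vector) against mean expression (log2 CPM over 6 libraries) of each gene tested, with the 484 genes called higher in red, the 275 called lower in blue and 12784 not called in grey. Triangles stand for genes beyond the axis, and GNA12 lies at -2.16, apart from the other genes of its expression level.

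Chaperone and unfolded protein response genes of the endoplasmic reticulum fell as a group. Of the 26 tested, 11 fell and 0 rose over all genes tested by edgeR (16 fell and 0 rose adjusted over the list alone), and 25 had a negative log2 fold change. The mean log2 fold change was -0.30 and camera gave an adjusted p = 5.83e-13, against an adjusted p = 0.106 with an estimated correlation. Besides HSPA5 (log2 fold change -0.74, SE 0.046, edgeR adjusted p = 5.27e-04; chromosome 9, 125234853 to 125241330), those that fell included PDIA4, a disulfide isomerase gene, from 324 ± 11.6 to 222 ± 7.74 CPM. HSP90B1, the gene of the chaperone GRP94, fell from 1078 ± 15.3 to 806.8 ± 14.03 CPM. SEL1L, a gene of the degradation complex of the endoplasmic reticulum, fell by 0.50 on the log2 scale. The list of integrated stress response genes, many of them induced by the factor ATF4, had 13 of 33 lower and 0 higher (21 lower and 0 higher adjusted over the list alone). Its mean was -0.31 and its median -0.26, with a camera adjusted p = 2.41e-11 and an adjusted p = 0.106 with an estimated correlation. ASNS, the asparagine synthetase gene, fell from 109 ± 2.81 to 66.8 ± 7.90 CPM (edgeR adjusted p = 0.00656), and STC2, a stanniocalcin gene, from 127 ± 2.75 to 86.5 ± 3.03 CPM. The 13 also held ALDH1L2, PSAT1 and MTHFD2 of serine and folate metabolism and the tRNA synthetase genes AARS1, WARS1, GARS1 and CARS1. DDIT3, which encodes the stress-induced factor CHOP, fell from 49.4 ± 9.50 to 22.2 ± 5.77 CPM, and its call was lost in 5 of the 6 fits without 1 library. The log2 fold change of DDIT3 was -1.15 (SE 0.228, edgeR adjusted p = 0.049) and lay between -0.98 and -1.38 without 1 library, with an adjusted p of 0.034 without overexpression replicate 1 and of 0.095 to 0.163 without any other.

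Genes of cholesterol synthesis rose as a group, 10 of 26 over all genes tested by edgeR and 0 lower (17 higher and 1 lower adjusted over the list alone). The mean log2 fold change was 0.20, with a camera adjusted p = 1.51e-08 and an adjusted p = 0.191 with an estimated correlation. LSS, the lanosterol synthase gene, rose from 124.5 ± 2.96 to 160.2 ± 7.10 CPM (log2 fold change 0.36, SE 0.049, edgeR adjusted p = 0.00998), and SQLE, IDI1 and SREBF2 were among the 10. Fatty acid synthesis genes had 8 of 21 higher and 0 lower (8 and 0 adjusted over the list alone), a mean of 0.16, a camera adjusted p = 2.48e-05 and an adjusted p = 0.106 with an estimated correlation. The desaturase gene FADS1 rose from 291 ± 12.3 to 369 ± 6.34 CPM, and FASN, the fatty acid synthase gene, from 499 ± 17.1 to 601.5 ± 13.4 CPM. The list of hypoxia and glycolysis genes had 12 of 36 higher and 1 lower (19 higher and 2 lower adjusted over the list alone), a mean of 0.16, a camera adjusted p = 4.54e-07 and an adjusted p = 0.288 with an estimated correlation. PKM, the pyruvate kinase gene, rose from 861 ± 13.5 to 1140 ± 49.5 CPM, and PFKL, TPI1, PGK1, GPI and ALDOC of glycolysis rose with the hypoxia-induced genes CA9, BNIP3 and EGLN1. ANGPTL4, the member that fell, had a log2 fold change of -0.43. Some hypoxia-induced members were not called and went either way, with VEGFA at -0.53, P4HA1 at -0.17, EGLN3 at 0.39 and KDM3A at 0.27. Nuclear genes of oxidative phosphorylation had 3 of 65 higher (COX6C, ATP5MC3 and ATP5MF) and 0 lower, with the same counts adjusted over the list alone, and 16 of the 65 at an unadjusted p under 0.05. Their mean was 0.11, with a camera adjusted p = 2.48e-05, an adjusted p = 0.569 with an estimated correlation and 0.205 with fry. Fry asks whether the list moved, on balance, in 1 direction and not whether it moved against other genes. Of the 6 fits without 1 library, ATP5MF lost its call in all 6, SREBF2 in 5, ATP5MC3 in 4, FASN in 3 and COX6C in 2. On the deposited TPM, limma-trend called 0 genes of the cholesterol, fatty acid and oxidative phosphorylation lists, with 16, 7 and 12 at an unadjusted p under 0.05, while DESeq2 called 15, 8 and 6 and limma-voom 10, 8 and 3.

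**Figure D2:**
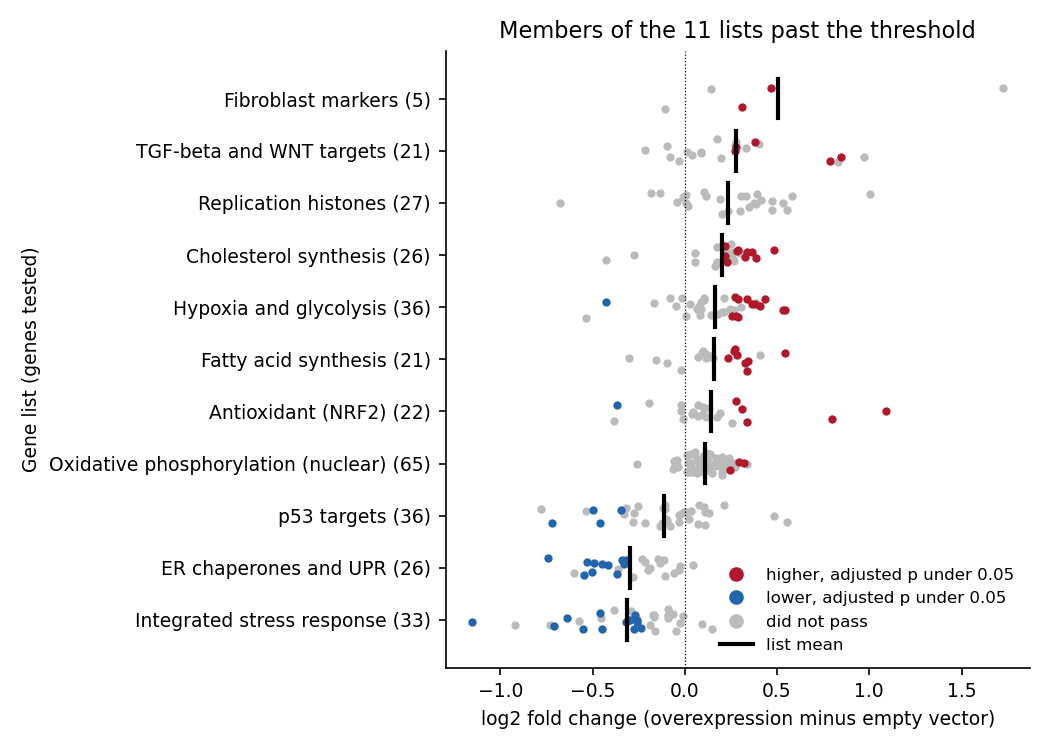
Log2 fold change (overexpression minus empty vector) of each tested member of the 11 lists that passed the camera test, 1 point per gene, red where called higher, blue where called lower and grey where not called. Black bars mark list means, which lie at -0.30 and -0.31 for the endoplasmic reticulum and integrated stress lists and at 0.20 for cholesterol synthesis.

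**Figure D3:**
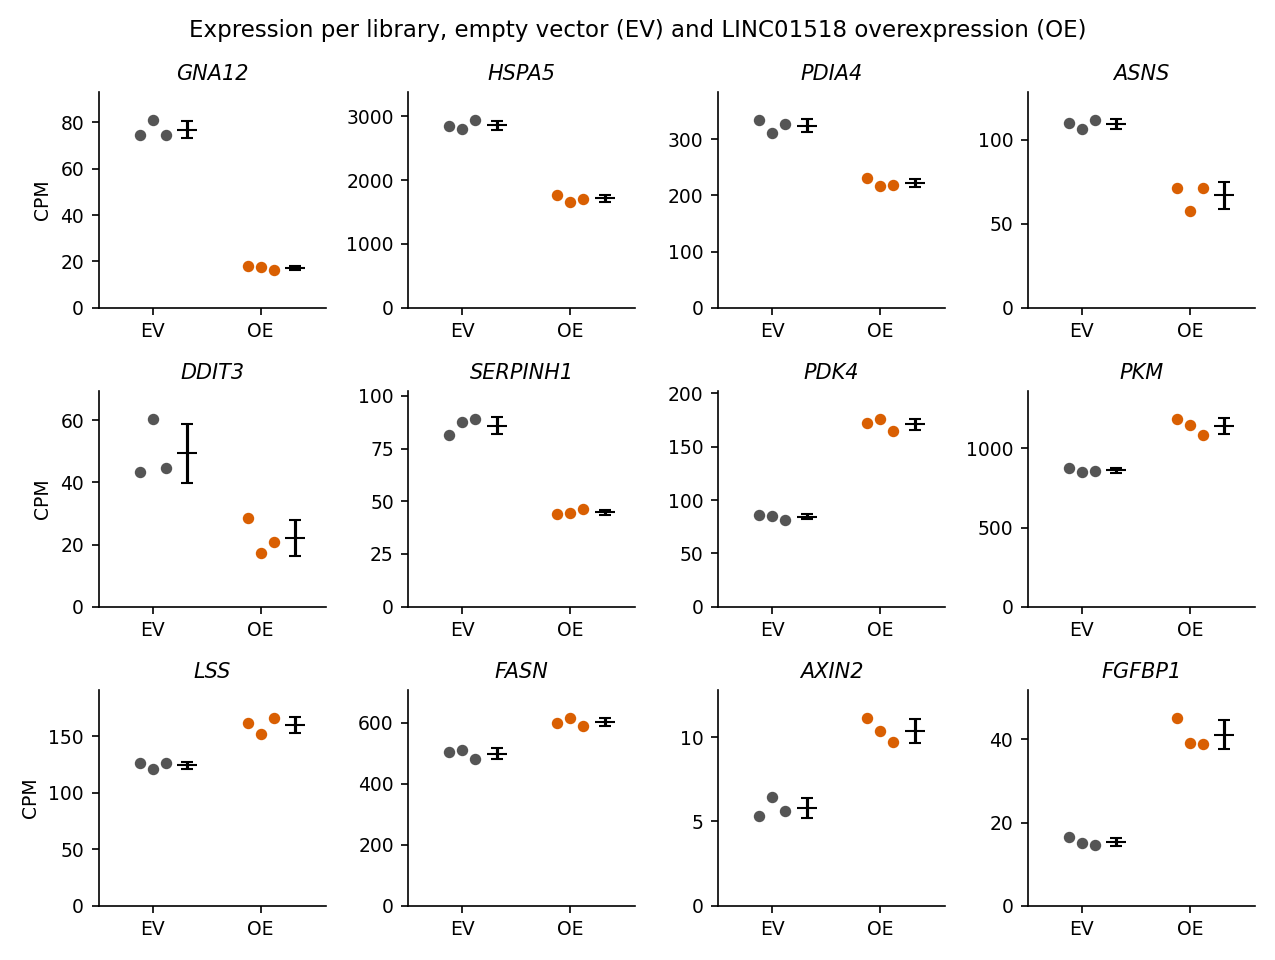
TMM-scaled CPM of 12 genes in each of the 6 libraries, 1 point per library, with the mean and SD of each group (n = 3) and axes from 0. GNA12 lies at 74.5 to 81.0 CPM in the empty vector libraries and at 16.3 to 17.9 CPM in the overexpression libraries.

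Targets of TGF-beta and WNT signalling had 5 of 21 higher and 0 lower (8 and 0 adjusted over the list alone), a mean of 0.28, a camera adjusted p = 7.03e-04 and an adjusted p = 0.106 with an estimated correlation. AXIN2, a feedback inhibitor gene of WNT signalling, rose from 5.78 ± 0.597 to 10.4 ± 0.717 CPM, and BAMBI, a decoy receptor gene of TGF-beta signalling, from 10.8 ± 0.825 to 18.7 ± 0.724 CPM. SMAD6, NKD2 and ID3 completed the 5, and all but ID3 encode inhibitors of these pathways. Antioxidant genes of the NRF2 list had 5 of 22 higher and 1 lower (7 higher and 3 lower adjusted over the list alone), a mean of 0.14, a camera adjusted p = 0.00708 and an adjusted p = 0.288 with an estimated correlation. PGD of the pentose phosphate pathway and NQO1 rose, as did AKR1C1 and AKR1C2, close paralogs whose reads can be shared, while the transporter gene ABCC3 had a log2 fold change of -0.37. The list of p53 targets had 4 of 36 lower and 0 higher (4 and 0 adjusted over the list alone), a mean of -0.11, a camera adjusted p = 0.025 and an adjusted p = 0.191 with an estimated correlation. GDF15 (106.9 ± 5.78 to 64.8 ± 3.89 CPM) and SESN2, both also induced by ATF4, fell with PLK3 and ZMAT3, and without empty vector replicate 3 the list's adjusted p was 0.0862. Fibroblast markers had 2 of 5 tested genes higher, COL1A1 (82.5 ± 3.64 to 114 ± 1.45 CPM) and PDGFRB, and 0 lower (3 and 0 adjusted over the list alone). Their mean was 0.51 and median 0.31, with a camera adjusted p = 0.025, an adjusted p = 0.286 with an estimated correlation, 0.0862 without empty vector replicate 3 and 0.0723 without a count filter. The largest of the 5 changes was that of COL3A1, at 1.73 with 6 to 53 counts per library (edgeR adjusted p = 0.0562). DCN was at 0.14, and COL5A1, the most abundant of the 5 at 448 CPM, at -0.11. Of the 12 fibroblast genes listed, 6 were at or under the floor in every library. PDGFRB had an edgeR adjusted p = 0.0471 and a log2 fold change of 0.31, which was -0.06 on TPM. Replication-dependent histone genes, which share sequence with one another, had a mean of 0.23, a camera adjusted p = 0.0294 and an adjusted p = 0.288 with an estimated correlation. Of 27 tested, 0 were called by edgeR over all genes or adjusted over the list alone, 0 by DESeq2, 0 by limma-voom and 0 on TPM, with 9 at an unadjusted p under 0.05. SMAD6, NKD2, ZMAT3 and PDGFRB each lost their call in all 6 fits without 1 library, PGD and AKR1C2 in 4, PLK3 in 2 and NQO1 in 1. The histone list did not pass without empty vector replicate 1 (adjusted p = 0.0742), without overexpression replicate 2 (0.0604) or with the stricter count filter (0.0784).

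The other 18 lists tested did not pass with camera. Androgen-induced genes had 2 of 29 higher and 2 lower (4 higher and 3 lower adjusted over the list alone; adjusted p = 0.851). Androgen-repressed genes had 0 of 6 called (2 higher and 1 lower adjusted over the list alone; 0.177). Luminal prostate markers had 1 of 14 called, KRT8 at 0.29, and neuroendocrine markers had 2 of 7 higher, SRRM4 and ENO2 (camera adjusted p = 0.115 and 0.177). Of the 20 neuroendocrine genes listed, 10 were at or under the floor in every library, and ENO2 is also in the hypoxia and glycolysis list. In the G1/S list, 6 of 45 genes rose, TYMS, MCM5, FEN1, E2F1, POLD3 and MCM2, and RAD51AP1 fell (0.0904), while 1 of 55 G2/M genes rose, PLK1 (0.288). Immediate early genes had 3 of 31 higher, among them JUND at 0.46, and 4 lower (0.078). Mesenchymal genes had 3 of 25 higher, SNAI2 (4.71 ± 0.0354 to 8.59 ± 0.606 CPM), CCN2 and CAV1 (0.540). NF-kappaB targets had 1 of 23 higher and 3 lower, with ICAM1 at -0.45 (0.282). Core apoptosis genes had 2 of 35 higher, CASP9 and BMF, and 1 lower, MCL1 (0.667), and heat shock genes 1 of 20 higher, CRYAB, and 1 lower, SERPINH1 (0.702). Mitochondrially encoded genes had 1 of 13 higher, MT-CYB (0.297). MYC targets (0.078), interferon-induced (0.540), autophagy and lysosome (0.595), endothelial (0.851) and ribosomal protein genes (0.954) had 0 called. Of the 232 members of the 7 lists without a call in edgeR, the androgen-repressed and histone lists included, 35 had an unadjusted p under 0.05, and DESeq2 called 7, limma-voom 1 and limma-trend on TPM 0. Of 15 immune markers 4 were tested, too few for the list test, and CD68, which epithelial lines also express, fell from 33.3 ± 0.906 to 21.2 ± 1.96 CPM (edgeR adjusted p = 0.00722). Of the 6 fits without 1 library, MCM5 and CCN2 lost their calls in 3, MCL1 in 2 and CASP9 in 1. Some of these lists passed without 1 library: MYC targets without empty vector replicate 2 (0.0358) or overexpression replicate 3 (0.0248), immediate early genes without empty vector replicate 2 (0.0358) and G2/M genes without empty vector replicate 1 (0.0196). G1/S genes passed without empty vector replicate 1 (0.00768) or overexpression replicate 2 (0.0194). Ribosomal protein genes passed lower without empty vector replicate 1 (1.13e-04) and higher without empty vector replicate 3 (0.00559).

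FKBP5, a gene induced by androgen and glucocorticoid, had 52.6 ± 2.20 CPM with empty vector and 38.2 ± 12.3 CPM with overexpression (log2 fold change -0.46, SE 0.254, edgeR adjusted p = 0.342). Of 58 androgen-induced or luminal prostate genes, 11 had 0 counts in all 6 libraries: KLK2, KLK3, KLK4, TMPRSS2, TRPM8, FOLH1, MAF, ORM1, ORM2, ESRP1 and KRT19. Changes in them were not detectable at this depth. Across the whole table, 4024 of 20263 genes had 0 counts in all 6 libraries. That share is similar, but the whole table also holds genes of other tissues, such as 410 immunoglobulin or T cell receptor segments. It is not the share to be expected of genes chosen as prostate markers. Of 20 luminal prostate markers, 14 were tested and the median level of the 20 was 5.51 CPM.

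**Figure D4:**
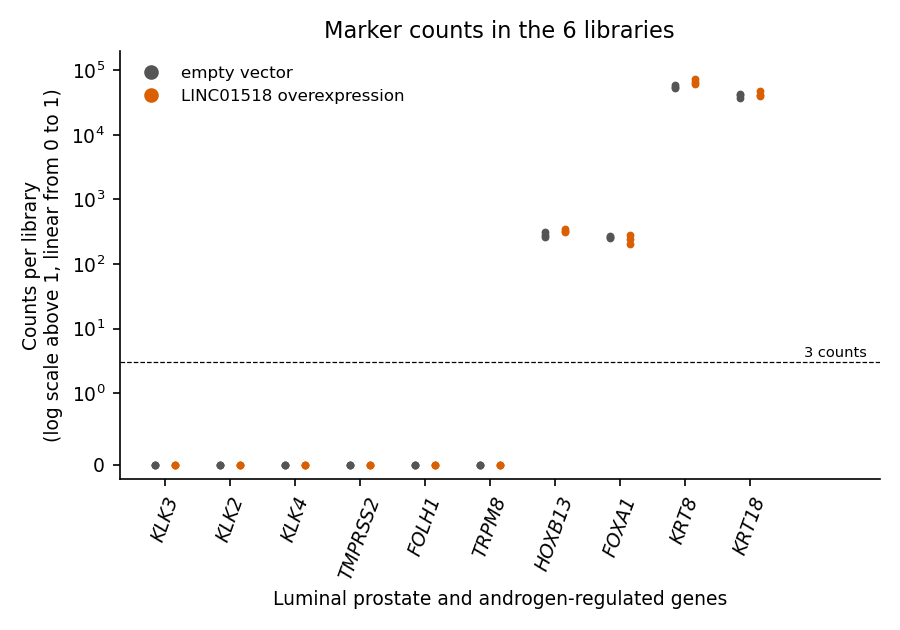
Counts per library, on an axis that is logarithmic above 1 and linear from 0 to 1, of luminal or androgen-regulated prostate genes, with 1 point per library and a dashed line at 3 counts. KLK3, KLK2, KLK4, TMPRSS2, FOLH1 and TRPM8 lie at 0 in all 6 libraries, whereas KRT8 has 53252 to 72353 counts.

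With 1 library left out, edgeR called fewer genes than the 759 called with all 6. It called 413, 278 and 458 without empty vector replicate 1, 2 or 3 and 232, 236 and 193 without overexpression replicate 1, 2 or 3. A fit with fewer libraries detects less, and 0 of the 759 had the other sign in these 6 fits. Of the 70 called genes named by the rule, 40 were called in each of these 6 fits. DESeq2 called 1316 genes, limma-trend on TPM called 219 (100 higher and 119 lower), and with library size as the only scaling edgeR called 346 higher and 382 lower, against 484 and 275 with TMM.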

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

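The correction for GC content and length and the counts over other splits were chosen after the results were seen, and the other alternatives were planned. The planned results for LINC01518 and MEG3 were not run. RLE scaling, upper-quartile scaling, library size only, both count filters, limma-voom, the fit without mitochondrial and ribosomal protein genes and the correction for GC content and length gave 720 to 905 called genes against 759. Of the 759, 621 were called with library size only, 649 after the correction for GC content and length and 688 to 758 in the others. DESeq2 called 1316 (784 higher, 532 lower), and 739 of the 759 were among them. Limma-trend called 219 (100 higher, 119 lower) on log2(TPM + 1) and 225 (103 higher, 122 lower) on log2(TPM + 0.1), and 2 of the 759 had the other sign in each. The share of higher calls was 63.8% with TMM, 57.5% with upper-quartile scaling, 47.5% with library size only and 45.7% on TPM. The test against a 1.5-fold change called 3 genes (2 higher, 1 lower), since it asks for a larger change. With 1 library fewer, 193 to 458 genes were called (131 to 287 higher, 62 to 171 lower), 413, 278 and 458 without empty vector replicates 1, 2 and 3 and 232, 236 and 193 without overexpression replicates 1, 2 and 3. Of the 70 named called genes, 24 lost their call without at least 1 library but not without each, and 6 (CCDC169, ATP5MF, NKD2, PDGFRB, SMAD6 and ZMAT3) lost it in all 6 such fits. On TPM, 24 of the 70 lost their call and kept their sign with a pseudocount of 1 and 25 with 0.1, among them SERPINH1, LSS, FADS1, EGLN1 and ALDH1L2, and PDGFRB lost its call and changed sign. The log2 fold change of PDGFRB was -0.059 and -0.063 on TPM. The mean of the ribosomal protein list lay between -0.061 (without empty vector replicate 1) and 0.06 (without empty vector replicate 3). The estimated correlation left 0 lists past the threshold, with 6 at an unadjusted p under 0.05 and a lowest adjusted p of 0.106. Fry, which tests for a shift of a list on balance in 1 direction and not against other genes, called 12, among them 10 of the 11 lists. Camera called 11 lists with RLE or upper-quartile scaling, 10 without a count filter, 9 with the stricter one, 10 to 13 without 1 library and 14 after the correction for GC content and length, and the 11 lists kept the sign of their mean under each scaling and on TPM. The cause was not tested for any of these changes except that of the 1.5-fold test. A fit without 1 library detects less for its smaller number of libraries, and what each library added beyond that was not tested. Replicate numbers were checked for pairing by the correlation of deviations from the group means, across genes, which are not independent: the same-numbered libraries gave 0.037, 0.055 and 0.045, all under 0.1, so they were treated as sharing only a number, although each library correlated best with its own number, a hint from the data and not the design. With the replicate number as a block, 232 genes were called (154 higher, 78 lower), 219 of them among the 759, and 11 lists. Of the 70 named called genes, 24 lost their call with the block. The real split of the 6 libraries gave 759 genes and the highest of the other 9 splits gave 5, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. In simulated data of this depth, 14% of genes given the smallest change, below 1.5-fold, were recovered, which limits what can be said of small changes. The changed genes all had mean counts well above the filter's minimum, so recovery of genes with fewer counts was not tested.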

Other observations

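The tests of gene families, chromosomes, splits of the libraries, prostate markers, GC content and length, glucose, copy number and antisense match were all chosen after the differences between the groups were seen, and what the last 4 would show was written before they were run.

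Genes of the PRAMEF family, which lie in a cluster on chromosome 1 and are paralogs of the cancer-testis gene PRAME, were higher with overexpression. Of 10 tested, 7 were called higher by edgeR (PRAMEF27, PRAMEF9, PRAMEF15, PRAMEF25, PRAMEF26, PRAMEF4 and PRAMEF7) against 0.357 by chance, with a median log2 fold change of 1.32 and an adjusted p = 7.08e-06 (Fisher's exact test, one-sided) over 908 tests of families by direction, of which 1 passed. PRAMEF9 rose from 3.92 ± 0.720 to 9.76 ± 1.87 CPM (SD, n = 3 each). The members share sequence, so their reads can be shared and the 7 calls are not independent. Each of the 10 had a positive log2 fold change under each scaling and on TPM, with medians of 0.67 to 1.32. PRAME itself, on chromosome 22, had a log2 fold change of -0.04 (adjusted p = 0.741). Of 46 tests of chromosomes by direction, 0 passed (lowest unadjusted p 0.0796).

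Single genes outside the rule also stood out, and were chosen after their values were seen. ATP1B3, which encodes a subunit of the sodium pump, rose from 570 ± 111 to 1021 ± 41.2 CPM (edgeR adjusted p = 0.0368). ALPP, a placental alkaline phosphatase gene whose reads can be shared with ALPG, rose from 400 to 634 CPM (adjusted p = 0.00179), and CGA, the alpha subunit gene of glycoprotein hormones, from 427 to 611 CPM (adjusted p = 0.0342). The readthrough gene C1QTNF3-AMACR had 0, 1 and 0 counts with empty vector and 136, 52 and 139 with overexpression. AMACR, which overlaps it, had 545, 555 and 356 against 282, 323 and 208 counts (edgeR adjusted p = 0.0582). C1QTNF3, which also overlaps it, had 154, 166 and 139 against 113, 18 and 51 counts (edgeR adjusted p = 0.226). Reads can be divided differently between these overlapping genes, which was not tested. CLDN4 had 106 counts in overexpression replicate 3 and 998 to 1227 in the other libraries.

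By camera with a preset correlation, the lists of endoplasmic reticulum chaperones and of the integrated stress response were lower and those of cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, and oxidative phosphorylation higher with overexpression, whereas 0 lists passed with an estimated correlation (lowest adjusted p = 0.106, 6 lists at an unadjusted p under 0.05). A bias of GC content or transcript length as the whole cause was argued against by the correction for both, after which 10 of the 11 lists still passed and the histone list, with a mean of 0.23 before and 0.18 after, did not (adjusted p = 0.0854). Less glucose left in the medium of the empty vector cells predicted the glucose-induced genes TXNIP and ARRDC4 to be higher with overexpression. TXNIP had a log2 fold change of -0.10 (-0.099, SE 0.078) and ARRDC4, not called, was at -0.42 (edgeR adjusted p = 0.10). Their levels were 12.5 and 3.29 CPM with empty vector and 11.7 and 2.45 CPM with overexpression. These values argue against a glucose difference only if both genes still responded to glucose. If glucose was spent in both groups, they could not show it. The real split gave 11 lists and the highest of the others 8, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. The other splits mix the groups, so part of a group difference can remain in them, and they do not measure false calls. A response to the insert and a difference in culture that is not recorded in the labels both stay open and untested.

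Prostate markers such as KLK3 and TMPRSS2 were at 0 counts in all 6 libraries, which is unlike LNCaP as it is usually described. Genes lost at random in counting or table building were argued against by 0 of the 77 ribosomal protein and 65 nuclear oxidative phosphorylation genes at 0 counts. LNCaP cells deprived of androgen would be expected to express the androgen-repressed genes UGT2B15, UGT2B17 and OPRK1, which had 0 counts in total over the 6 libraries. Cells of another line and a loss of these markers in the LNCaP stock used both stay open, and the pattern was present in both groups.

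GNA12 had the largest fall among the called genes with a mean log2 CPM of at least 1. A copy number change of the wider region was argued against by the 13 other tested genes within 1 Mb, with a median log2 fold change of 0.067, although AMZ1, the gene that overlaps GNA12, was at -0.55 (SE 0.256, edgeR adjusted p = 0.241), so a change limited to this locus is not excluded. A long exact antisense match of LINC01518 to GNA12 was argued against by the longest one between their annotated transcripts, 9 bases, a length that 300 of 300 random genes of similar length reached. A change at the GNA12 locus itself, such as a vector inserted there or a clone that carries a lesion, stays open and was not tested, as do imperfect pairing and any other regulation by the insert, which was not checked and for which MEG3 was not searched.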
